A study of Mus musculus with 10 samples.

How the data were processed

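Total RNA from the whole brains of 5 Glo1 transgenic (Tg) and 5 wild-type (WT) littermates was isolated with TRIzol, cleaned up on RNeasy columns, labelled with biotin and hybridised to 1 Affymetrix mouse gene array per mouse, per the labels' protocols. The labels call the samples of each group biological replicates. Arrays were processed in Affymetrix Expression Console 1.1.2, per the submitters' processing notes; its background correction, normalization and summarisation settings are not given in the sources used here. The deposited values are log2 expression values, as their range of 3.28 to 14.7 over 35556 rows shows, and they were used without further normalization. An array measures brightness and not molecules, so fold changes on it can understate true ratios, more so for dim probe sets. The scanner files were not used here, so signal over background could not be set per array.

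Rows whose identifiers come before the first transcript cluster were taken as the platform's controls and left out. They were 6612 rows, 18.6% of the table, and none was paired with a gene in the annotation table used. The remaining 28944 probe sets were tested. Genes came from the platform annotation: 21789 probe sets had 1 gene, 1621 had several and 5534 were unnamed here. No gene was named from a probe set with several. Symbols were updated through Entrez identifiers, and 21698 of the 21789 matched the mouse annotation of assembly GRCm38.p6, while 91 kept their platform symbol. That assembly served only for symbols, chromosomes, the 1 Mb window around Glo1 and gene order; coordinates are not printed, since the sources used here name no build. The 19938 genes with a value were each represented by their brightest probe set over all 10 arrays.

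Tg and WT were compared per probe set with limma 3.58.1 (lmFit and eBayes, without covariates) in R 4.3.3, with Benjamini-Hochberg adjustment over the 28944 probe sets and a threshold of 0.05. Differences are Tg minus WT in log2 units, with 95% confidence intervals. Values of single genes and list means were also tested with two-sided exact permutation tests over all 5 against 5 assignments. Gene lists were tested at gene level with camera at its preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over 30 lists with at least 5 measured members. Glo1 was left out of every list. Clustering of called genes on chromosomes was tested with one-sided Fisher's exact tests. The limma step was tested on simulated data with known differences in some of the 28944 probe sets between 5 and 5 arrays. It recovered 93% of 100 probe sets changed by 0.5 log2 units and 100% of 100 changed by 1, with 16 false calls among 209. The simulated noise was independent between probe sets and held no outlying array. Far more probe sets were changed than passed in the data, which eases the adjusted threshold. These rates therefore show that the step works, and do not give its power in the data.

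The groups, main tests, gene lists, naming rule and all but 3 alternatives were fixed before the data were examined; those alternatives and the further tests chosen later are named as such where reported. The 32 lists held 651 members, of which 599 had a value. The functional lists covered methylglyoxal handling, glutathione, Nrf2 targets, glycolysis, oxidative phosphorylation, GABA-A receptors, inhibitory neurons, glutamate receptors, anxiety and stress signalling, immediate early genes, heat shock and unfolded protein response, inflammation and the circadian clock. The marker lists covered 17 cell types, brain regions and adjoining tissues, and 2 further lists held the neighbours of Glo1 and sex-linked genes. The other members were not analysed here. Some genes sit in more than 1 list, such as Eomes in the cerebellar and olfactory bulb lists.

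The text names Glo1 with all its probe sets and genes past the threshold, up to 10 per direction. Where fewer than 10 passed in a direction, genes of lowest unadjusted p filled that direction up to 6. It also names the member of lowest p of each functional list and members past the threshold over a list alone, up to 4. It names the member of lowest p of each marker list that camera called or that had such a member. It further names 4 genes beside Glo1 and the 6 brightest GABA-A receptor subunits. Gpr85, Nxph1, Mdfic, the dim genes of the chromosome 6 stretch, Prl, Gh, Gabra6 and the other cerebellar and pituitary genes of the closing section were chosen after their values were seen, except 12 cerebellar genes outside the list, which were chosen before. Alternatives covered other normalizations between arrays, filters on dim probe sets, other variance models, array weights, the replicate number as a block, the serial number in the labels as a covariate, another summary per gene, other set tests, a minimum fold and leaving out each array in turn. Depth in reads does not apply to arrays; the number of arrays limits the precision.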

Results

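Whole-brain RNA was profiled from 5 mice that carried Glo1 on a bacterial artificial chromosome transgene (Tg) and from 5 wild-type littermates (WT). All were untreated adult males on a C57Bl/6J background. Glo1 encodes glyoxalase 1, which detoxifies methylglyoxal, a reactive by-product of glycolysis, with glutathione as cofactor. Each mouse was measured on its own single-channel Affymetrix gene array, so each group held 5 biological replicates. The median log2 value of the 28944 probe sets tested lay between 7.95 and 8.05 on the 10 arrays. WT replicate 2 had the lowest mean correlation with the other arrays across probe sets (r = 0.992, against 0.994 to 0.997). The Y-linked genes Eif2s3y, Uty and Kdm5d were read at 9.13 to 10.27 log2 units on every array, and Xist at no more than 5.88, as in male tissue.

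The first comparison asked how strongly Glo1 was expressed in the transgenic brain. Glo1 was 2.84-fold higher in Tg than in WT brain (95% confidence interval 2.51 to 3.20). On probe set 10449644, which gave this fold, the mean was 11.97 ± 0.12 log2 units in Tg (SD, n = 5) and 10.47 ± 0.16 in WT (SD, n = 5). The difference was 1.50 log2 units (SE 0.081, limma adjusted p = 1.53e-05). All 5 Tg values lay above the highest WT value (two-sided exact permutation p = 0.007937, the smallest that 5 against 5 arrays can give). A second probe set annotated to Glo1, 10471675, gave a 2.85-fold difference (2.47 to 3.27, limma adjusted p = 3.50e-05), from 10.57 ± 0.19 in WT to 12.08 ± 0.13 in Tg (SD, n = 5 each), with the same exact permutation p of 0.007937. Glo1 lies on chromosome 17, and the mouse annotation also lists a Glo1 pseudogene on chromosome 2. Which of these copies the probes of each set match was not tested, so the separate level of either copy is uncertain.

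**Figure D1:**
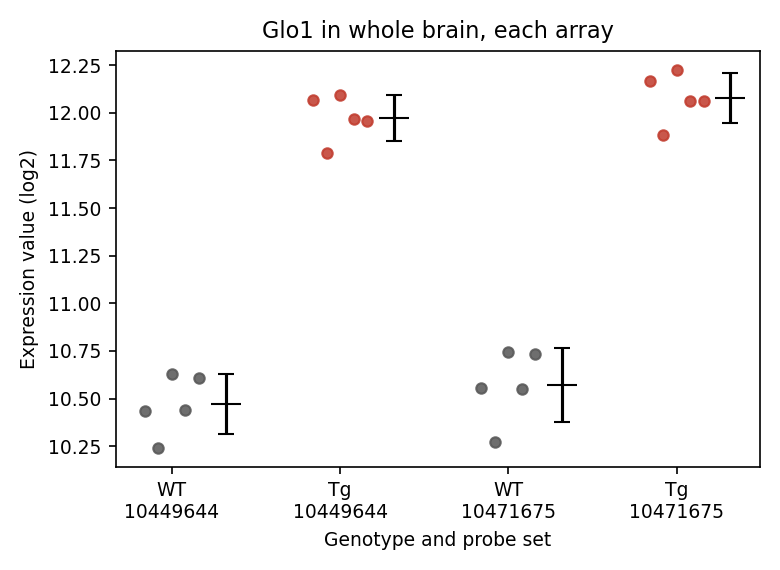
Log2 expression value of Glo1 (vertical axis) on each of the 10 arrays, for both probe sets annotated to the gene, by genotype. Points are single mice, and the black marks are group means with 1 SD. Tg arrays lie between 11.79 and 12.10 on probe set 10449644, above the WT range of 10.24 to 10.63.

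The second comparison asked which other transcripts differed between Tg and WT brain. Apart from Glo1, the genes past the threshold were 8 neighbouring genes of chromosome 6, and all 8 were lower in Tg. They were Ndufa4, a subunit associated with cytochrome c oxidase; Phf14, a PHD finger protein; Thsd7a, a thrombospondin-domain membrane protein; Tmem106b, a lysosomal membrane protein; Tmem168; Bmt2; 2610001J05Rik; and Foxp2, a forkhead transcription factor. Tg levels of the 9 brighter genes in this stretch, these 8 and Gpr85, ranged from 53.2% to 65.3% of WT levels, with a mean difference of -0.74 log2 units. Bright here means a mean in the upper 60% of probe sets.

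Phf14 showed the lowest ratio, from 9.61 ± 0.13 log2 units in WT to 8.70 ± 0.13 in Tg (SD, n = 5 each). Its difference was -0.91 (SE 0.077, limma adjusted p = 3.49e-04). Ndufa4 went from 11.08 ± 0.040 to 10.29 ± 0.095, a difference of -0.79 (SE 0.050, limma adjusted p = 3.67e-05). Tmem106b differed by -0.80 (limma adjusted p = 0.00193) and 2610001J05Rik by -0.74 (limma adjusted p = 0.00463). Thsd7a differed by -0.67 and Foxp2 by -0.64, both with a limma adjusted p of 4.94e-05. Foxp2 read 9.28 ± 0.062 in WT and 8.64 ± 0.048 in Tg. Tmem168 differed by -0.62 (limma adjusted p = 1.82e-04) and Bmt2 by -0.78 (limma adjusted p = 0.0423). Bmt2 passed the threshold less firmly: leaving out any array except WT replicate 2 ended its call, with an adjusted p of up to 0.192, and median centring ended it as well (adjusted p = 0.0968). Tested against a minimum change of 1.2-fold, Bmt2, Tmem106b and 2610001J05Rik did not pass and the other 5 genes did. For each of the 8 genes, all 5 Tg values lay below the lowest WT value (exact permutation p = 0.007937).

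The 8 genes lie within 1 stretch of 12 measured genes, from Ndufa4 to Foxp2, in the gene order of assembly GRCm38.p6. Chromosome 6 held 8 called genes among 1099 tested, against 0 on all other chromosomes with Glo1 left out (one-sided Fisher's exact test, adjusted p = 1.89e-09). That test counts genes as independent, while these 8 lie in 1 stretch and were measured in the same mice, so its p overstates the evidence. Gpr85, a G protein-coupled receptor within the stretch, differed by -0.69 and missed the threshold (limma adjusted p = 0.0609); it passed in 8 of 21 alternatives, among them the fit without WT replicate 2 (adjusted p = 0.00230). The remaining 3 genes, Gm6578, Vwde and Ppp1r3a, were dim in brain, and their differences lay between -0.08 and -0.01. On one side the next gene was Nxph1, with a difference of -0.31 (SE 0.049, limma adjusted p = 0.125) and all 5 Tg values below the lowest WT value. Nxph1 passed when its probe sets were averaged (adjusted p = 0.0349) and among the upper 30% of probe sets (adjusted p = 0.0328). On the other side Mdfic differed by -0.14 (exact permutation p = 0.0238, limma adjusted p above 0.99). Beyond these, the 10 nearest bright genes had a median difference of -0.029 on the Nxph1 side and -0.026 on the Mdfic side. The mean of the 9 bright genes was 9.65 ± 0.093 in WT and 8.91 ± 0.053 in Tg (SD, n = 5 each, exact permutation p = 0.007937). These 9 genes were chosen by their place between the called genes, so that test is not independent of the calls.

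**Figure D2:**
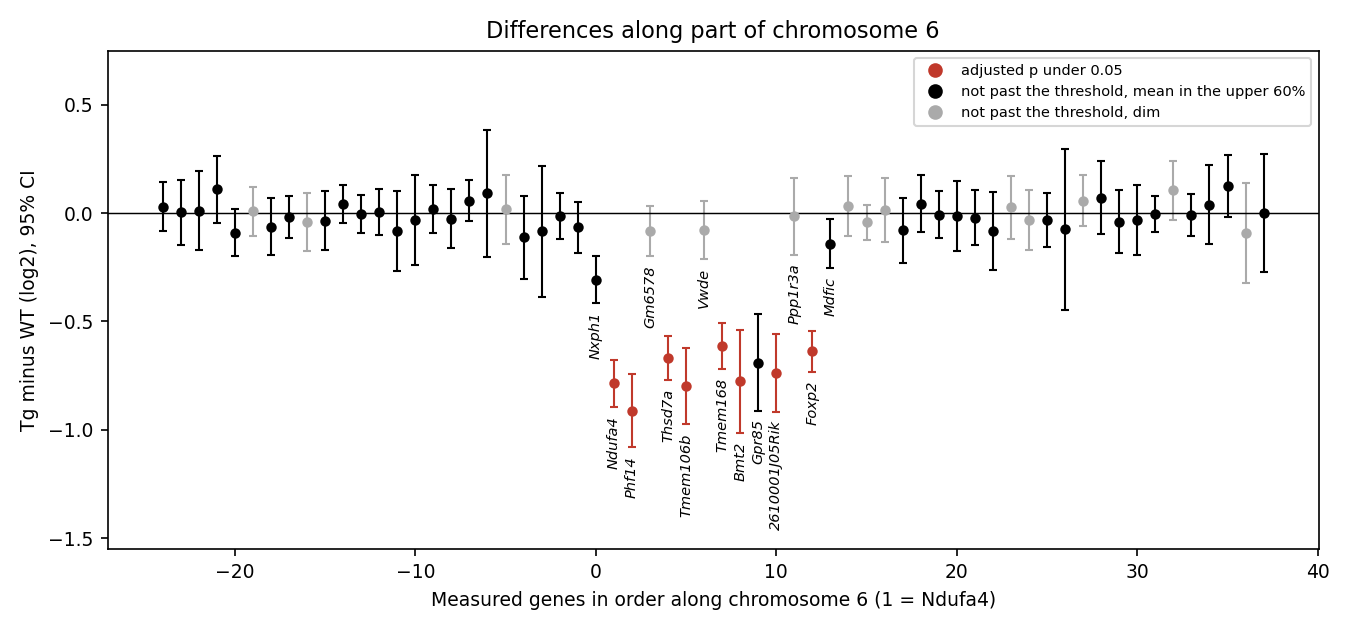
Difference between Tg and WT brain in log2 units (vertical axis) for measured genes in their order along chromosome 6 (horizontal axis, 1 is Ndufa4). Points are gene estimates from 5 against 5 mice with 95% confidence intervals; red marks genes past the adjusted threshold and grey marks dim genes. The 9 bright genes of the stretch lie between -0.91 and -0.62, while the 10 bright genes beyond each flank lie between -0.11 and 0.09.

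In all, 2 probe sets were higher in Tg, both of Glo1, and 8 were lower. At an unadjusted p under 0.05, limma gave 285 higher and 355 lower probe sets, 640 in total, where chance alone gives about 1447; without WT replicate 2 the total was 3189. The genes with the next lowest p values above Glo1 had small differences that did not pass: Mlph, which links melanosomes to myosin, at 0.16, E130309D02Rik at 0.18, A430093F15Rik at 0.15 and Kbtbd6 at 0.19. Their adjusted p values all exceeded 0.99. The median SE was 0.063 log2 units per probe set. Precision is limited by the number of arrays and, for some genes, by the spread that WT replicate 2 added. Without that array the SE fell from 0.109 to 0.066 for Bmt2, while it rose from 0.077 to 0.081 for Phf14. The count of 640 against about 1447 therefore does not show that few transcripts differ.

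A bacterial artificial chromosome can carry genes that flank its target, so the genes beside Glo1 on chromosome 17 were compared as a list. Btbd9, a BTB-domain protein gene next to Glo1, was 0.26 log2 units higher in Tg (SE 0.057), at 10.73 ± 0.10 against 10.47 ± 0.069 in WT (SD, n = 5 each). It was the 1 member of 26 measured to pass when adjusted over the list alone (limma adjusted p = 0.0179), and it did not pass over all probe sets (adjusted p above 0.99). Its call ended without WT replicate 1 (adjusted p = 0.0585) or WT replicate 3 (0.0597). All 5 Tg values exceeded the highest WT value (exact permutation p = 0.007937). Dnah8, an axonemal dynein gene that was dim in brain, differed by 0.16 (limma adjusted p = 0.152 over the list alone). Without WT replicate 2, 4 members passed over the list alone, Btbd9, Dnah8, Umodl1 and Tff1. Zfand3 differed by 0.00098 (95% interval -0.11 to 0.11) and Glp1r, the glucagon-like peptide 1 receptor, by 0.04 (-0.16 to 0.24). The other members lay between -0.07 and 0.13. Among the 21 measured genes within 1 Mb of Glo1, Btbd9 again was the 1 past the threshold (adjusted p = 0.0145).

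Other genes of methylglyoxal handling did not differ detectably. Of 14 measured members, which include glyoxalase 2 (Hagh), the aldo-keto reductase Akr1b3 and the aldehyde dehydrogenase Aldh2, 0 passed adjusted over the list alone or over all probe sets. The lowest p belonged to Glod4, a glyoxalase-domain gene, at -0.11 (95% interval -0.23 to 0.02). The list mean differed by -0.010 (-0.058 to 0.037; camera adjusted p = 0.691). In the glutathione list 0 of 34 members passed, and the list mean differed by -0.0016 (-0.052 to 0.048; camera adjusted p = 0.848). Gstm4, a glutathione transferase, differed by -0.11, and by -0.061 without Tg replicate 5. Of 22 targets of the oxidative stress regulator Nrf2, 0 passed; Srxn1, sulfiredoxin, differed by 0.07, and the list mean by 0.0010 (-0.035 to 0.037; camera adjusted p = 0.848). Glycolysis genes, the source pathway of methylglyoxal, had 0 of 19 members past the threshold. Ldhb, a lactate dehydrogenase subunit, differed by 0.07 and the list mean by 0.0046 (-0.036 to 0.045; camera adjusted p = 0.571). Among the upper 30% of probe sets camera called the glycolysis list (adjusted p = 0.0462, but 0.538 with an estimated correlation). With single arrays left out its mean ranged from -0.0034 without WT replicate 5 to 0.018 without WT replicate 2, and Ldhb differed by 0.041 without WT replicate 4. Of 50 measured oxidative phosphorylation genes, Ndufa4 was lower and the other 49 did not pass. The mean of that list, with Ndufa4 at -0.79 included, differed by -0.019 (camera adjusted p = 0.571), and by -0.0068 without Tg replicate 5. Its median difference was -0.0065. For glutathione, Nrf2 targets and glycolysis, list mean and median had opposite signs.

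Methylglyoxal is known to act on GABA-A receptors, and their genes were examined next. None of 15 measured GABA-A receptor genes passed over the list alone. The 6 brightest subunits were close to equal in the 2 genotypes: Gabrb2 differed by -0.02 (95% interval -0.10 to 0.07), Gabra3 by 0.01 (-0.10 to 0.13) and Gabrb1 by -0.04 (-0.13 to 0.06). Gabra5 differed by 0.05 (-0.08 to 0.18), Gabra4 by -0.03 (-0.14 to 0.08) and Gabrg3 by -0.06 (-0.18 to 0.07). The signs of Gabra3 and Gabra4 changed when single arrays were left out. Gabrq, the member with the lowest p, differed by -0.13 (-0.27 to 0.0011; limma adjusted p = 0.775 over the list alone). Gabra6, the cerebellar granule cell subunit, had a difference of 0.75 with an interval from -1.14 to 2.63, set by WT replicate 2, where it read 6.03. Without that array Gabra6 differed by -0.29 and was the 1 member past the threshold over the list alone. The list mean was 0.030 higher and its median -0.018, with opposite signs (camera adjusted p = 0.571, direction down). Without WT replicate 2 the list mean was -0.030 (camera adjusted p = 0.187).

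**Figure D3:**
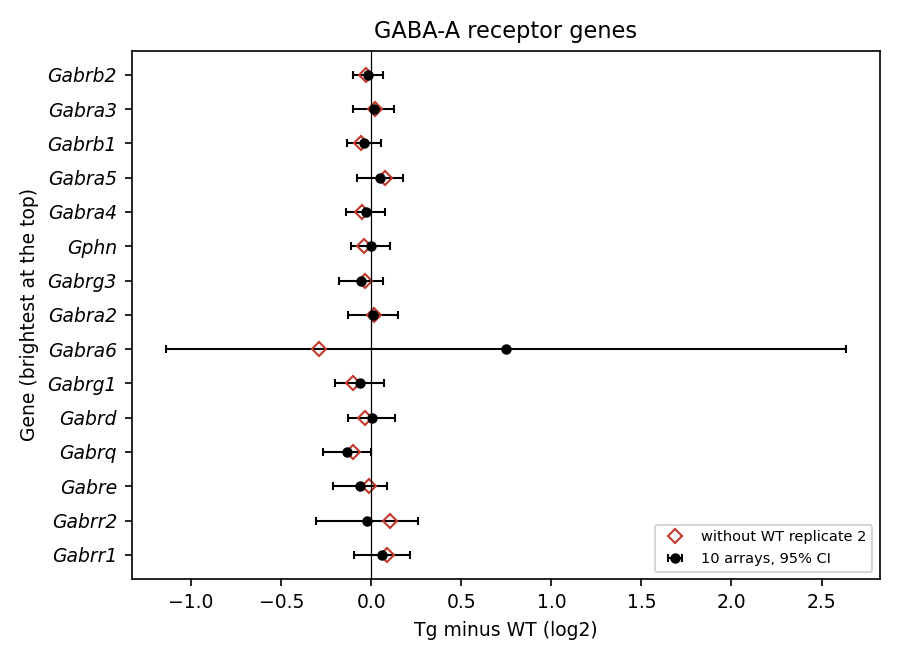
Difference between Tg and WT brain in log2 units (horizontal axis) for 15 GABA-A receptor and anchoring genes (vertical axis, brightest in WT at the top). Black points show all 10 arrays with 95% confidence intervals, and red diamonds the estimate without WT replicate 2. All intervals include 0, and Gabra6 moves from 0.75 to -0.29 without that array.

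Lists of neuronal signalling and of inflammation held 0 members past the threshold. Genes of inhibitory neurons (21 measured) had a mean difference of 0.040 (camera adjusted p = 0.401, and 0.0290 without Tg replicate 5, there 0.780 with an estimated correlation). Without Tg replicate 3 that mean was 0.014 (camera adjusted p = 0.925). Dlx2, an interneuron transcription factor, differed by 0.28 (limma adjusted p = 0.390 over the list alone). Glutamate receptor genes (27 measured) averaged -0.014 (camera adjusted p = 0.333; -0.020 to -0.0068 with single arrays left out), with Grik4, a kainate receptor subunit, at -0.11, and at -0.052 without WT replicate 2. Anxiety and stress signalling genes (33 measured) averaged -0.015 (camera adjusted p = 0.571) and 0.0081 without WT replicate 2, and Penk, the enkephalin precursor, differed by -0.06. Immediate early genes (22 measured) averaged -0.053 (camera adjusted p = 0.178). Without Tg replicate 5 or WT replicate 1 camera called that list (adjusted p = 0.00756 and 0.0112, but 0.780 and 0.836 with an estimated correlation), and without WT replicate 2 its mean was -0.017. Fos, a gene induced by neuronal activity, read 7.65 ± 0.14 in WT and 7.40 ± 0.13 in Tg, a difference of -0.25 (limma adjusted p = 0.187 over the list alone). Inflammation genes (24 measured) averaged 0.0024 with a median of 0.017 (camera adjusted p = 0.419); with single arrays left out the mean ranged from -0.015 without WT replicate 3 to 0.032 without WT replicate 2. Ifit1, an interferon-induced gene, differed by 0.25, and by 0.16 without Tg replicate 3.

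Of the 13 functional lists, 2 passed the camera test at its preset correlation, although no member of either passed over the list alone. Circadian clock genes had 14 of 16 members lower in Tg, with a mean difference of -0.067 (95% interval -0.14 to 0.0013; camera adjusted p = 0.00116). With an estimated correlation the adjusted p was 0.578, so that call was lost. Per3, a period clock gene, differed by -0.14, with all 5 Tg values below the lowest WT value. Heat shock and unfolded protein response genes had 25 of 26 members higher in Tg, with a mean difference of 0.064 (-0.14 to 0.27; camera adjusted p = 0.00138). With an estimated correlation their adjusted p was 0.886. Leaving out Tg replicate 4, Tg replicate 5 or WT replicate 2 ended this call even at the preset correlation (camera adjusted p = 0.0775, 0.575 and 0.429), as did array weights (0.249). The mean fell to 0.00095 without Tg replicate 5 and rose to 0.12 without WT replicate 5. Trib3, a stress-induced pseudokinase, differed by 0.12.

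Markers of brain regions moved with WT replicate 2. All 14 striatal markers had lower means in Tg, with a mean difference of -0.094 (95% interval -0.19 to 0.0028; camera adjusted p = 2.05e-06, estimated correlation adjusted p = 0.578). Rgs9, a striatal regulator of G protein signalling, differed by -0.15, and by -0.095 without WT replicate 2. Without WT replicate 2, where the striatal list was highest, the list mean was -0.050 (camera adjusted p = 0.0109, estimated correlation adjusted p = 0.193). Cerebellar markers had 16 of 18 members higher in Tg and a mean difference of 0.24 (-0.50 to 0.98; camera adjusted p = 0.00624, estimated correlation adjusted p = 0.886). That direction rested on WT replicate 2, whose list mean of 8.59 stood against 10.32 to 10.38 on the other WT arrays. Without that array the direction reversed, to -0.11 (camera adjusted p = 6.19e-09, estimated correlation adjusted p = 0.193). All 14 olfactory bulb markers were higher in Tg, at 0.18 on average (-0.033 to 0.40; camera adjusted p = 1.39e-05, estimated correlation adjusted p = 0.726); without WT replicate 2 the camera adjusted p was 0.102, and without Tg replicate 3 the mean was 0.12 (camera adjusted p = 0.0331). Eomes, expressed in olfactory bulb and cerebellum, differed by 0.56 (exact permutation p = 0.0476). Hindbrain and midbrain markers averaged 0.049 (camera adjusted p = 0.0222, estimated correlation adjusted p = 0.886). Leaving out Tg replicate 1, 3 or 4 or WT replicate 1 or 4 ended that call, with adjusted p values from 0.0775 to 0.567, as did quantile normalization (0.0977), cyclic loess (0.0869) and the first principal component as a covariate (0.120). The mean of that list was 0.089 without WT replicate 2 and 0.014 without WT replicate 4. Hoxa5, a hindbrain homeobox gene, differed by 0.11. Among these region lists, 0 members passed over the list alone. By fry, 0 of all 30 lists passed.

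The remaining marker lists did not pass the camera test. Among cell types, the mean difference was -0.0049 for neurons (16 genes), 0.015 for astrocytes (14) and -0.016 for oligodendrocytes (17). It was 0.0058 for microglia (15), 0.020 for vascular cells (18), 0.0061 for choroid plexus (16) and 0.0075 for ependyma (11). Meningeal markers averaged -0.0012 (15 genes), blood markers -0.082 (7), and pineal and retinal markers 0.029 (6). Cortical and hippocampal markers averaged -0.017 (19 genes), and thalamic and hypothalamic markers -0.032 (18). Mean and median had opposite signs for microglia, choroid plexus, meninges and blood. The lowest camera adjusted p among these lists was 0.178, for vascular markers. Several of these small means depended on single arrays. Without WT replicate 2 the mean was 0.025 for blood, 0.065 for pineal and retinal, 0.020 for thalamic and hypothalamic, 0.0051 for cortical and hippocampal and 0.013 for meningeal markers. It was -0.020 for choroid plexus, -0.0045 for astrocytes, 0.038 for microglia, 0.026 for ependyma, -0.0083 for oligodendrocytes and -0.00052 for neurons, and none of these lists passed camera there. Without WT replicate 4 it was 0.00092 for pineal and retinal, -0.013 for microglia, -0.012 for ependyma and -0.051 for thalamic and hypothalamic markers. Over all 30 lists, the circadian clock list was the 1 whose mean neither changed sign nor moved by over 1.5 times with any array left out. Pituitary markers averaged 0.044 (9 genes, 95% interval -1.26 to 1.35; camera adjusted p = 0.551), with a wide interval because replicate 2 of both genotypes read them far above the other arrays. Without WT replicate 2 their mean was 0.53 (camera adjusted p = 0.0109, estimated correlation adjusted p = 0.882), and without Tg replicate 2 it was -0.35. Prl, the prolactin gene, read 12.48 in WT replicate 2 and 12.09 in Tg replicate 2, and at most 6.62 elsewhere. Gh, the growth hormone gene, read 13.46 and 13.14 there, and at most 8.25 elsewhere. Prl and Gh differed by 0.14 and 0.09 between genotypes, and neither difference exceeded the spread between replicates.

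**Figure D4:**
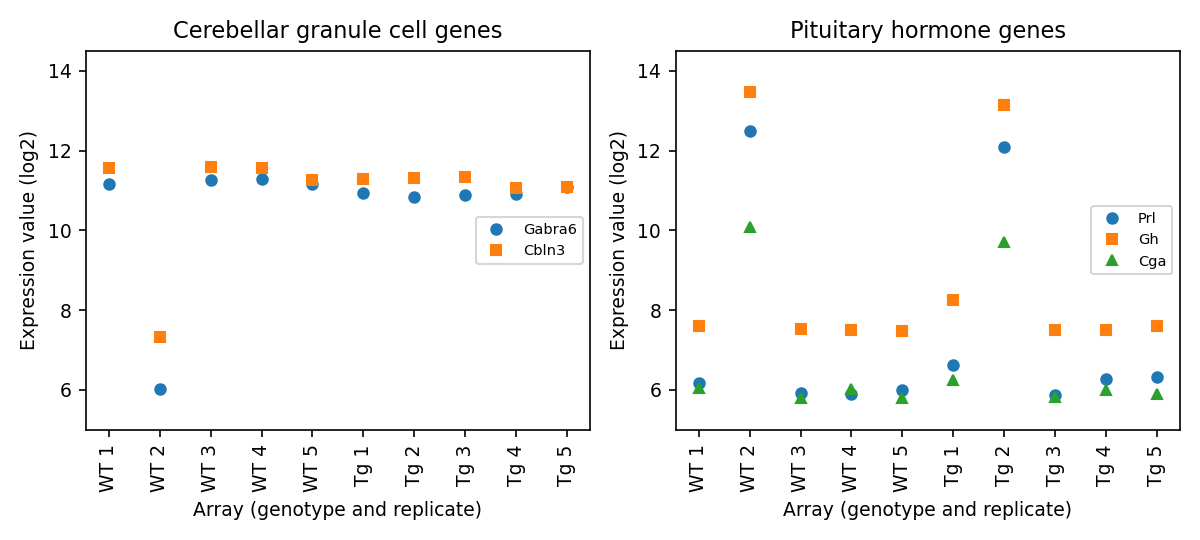
Log2 expression values (vertical axes) on each of the 10 arrays, named by genotype and replicate (horizontal axes), for cerebellar granule cell genes on the left and pituitary hormone genes on the right. Each point is 1 array. Gabra6 and Cbln3 are lowest in WT replicate 2, at 6.03 and 7.34, and Prl, Gh and Cga are highest in replicate 2 of both genotypes.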

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

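The tests of array quality on the chromosome 6 genes, of copy loss and sequence variants there, and on the cerebellar genes were chosen after those patterns had been seen; the values of the 12 cerebellar genes outside the list were then still unseen. The pituitary tests were set after the levels of Prl and Gh had been seen, but before those of the other pituitary markers or the effect of the covariate. Values were examined in 150 groups of 5 arrays, and in 27 of them 1 array stood far from the other 4, where chance gives about 8. Most of these lay in WT replicate 2 and share arrays and genes, so they are not independent.

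Cerebellar transcripts were low in WT replicate 2. Its cerebellar list mean was 8.59 against 10.32 to 10.38 on the other WT arrays; Gabra6 was 5.02 log2 units below the mean of the other 9 arrays, Cbln3 4.01, Car8 3.15 and Neurod1 2.91. A quality fault that lowers region markers in general would lower other regions as well. Instead, 3 of 3 lists for cortex and hippocampus, striatum, and thalamus and hypothalamus were higher there than on each other WT array. Other faults of array quality, which could raise some lists, were not tested. A brain sample lacking part of its cerebellum remains a candidate explanation. The list showed the pattern and so cannot test it; instead 12 cerebellar genes outside the list were set before their values were seen (Fat2, Cdh15, Tiam1, Chn2, Mab21l1, Ppp1r17, Rgs8, Homer3, Gng13, Dner, Gdf10 and Tfap2b). Of these 12, all bright, 100% were lowest in WT replicate 2 among the 10 arrays, with a median deficit of 0.857 log2 units and a range from 0.218 to 3.70. No biological explanation was tested, since 1 array of a group cannot be tied to genotype.

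Pituitary hormone genes were high in replicate 2 of both genotypes. Prl read 12.48 in WT replicate 2, against 5.89 to 6.17 on the other WT arrays, and 12.09 in Tg replicate 2, against 5.87 to 6.62 on the other Tg arrays. Gh read 13.46 against 7.47 to 7.60 in WT, and 13.14 against 7.50 to 8.25 in Tg; the pituitary list mean was 9.22 against 6.71 to 6.87, and 8.91 against 6.85 to 6.99. The first principal component of all arrays as a covariate shrank the excess of Prl and Gh by only 4.31%, which argues against uneven array quality as measured by that component. Pituitary tissue left on these brains may account for the excess. The other 7 measured markers had a median excess of 0.887 log2 units, led by Cga at 3.95, although Cyp11a1 showed -0.027. Both genotypes hold 1 such array, so genotype does not explain it, and no other biological explanation was tested.

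The 8 called genes of chromosome 6, from Ndufa4 to Foxp2, were lower in all 5 Tg arrays. The first principal component as a covariate shrank the median difference by 4.32%, from -0.76 to -0.72. Its scores overlapped widely between genotypes, at -9.23 to 10.7 in Tg and -23.5 to 34.0 in WT. A covariate so little tied to genotype could hardly shrink a difference between genotypes, so it cannot decide on uneven array quality. Only the outermost called genes, Ndufa4 and Foxp2, set the ends of the stretch, so bright genes between them could have been unchanged. All 9 bright genes of the stretch were lower, with differences of -0.91 to -0.62, and 0 lay within 0.2 of 0. Sequence variants of another strain under the probes would be likely to spare some genes. The values therefore argue against such variants as the sole cause for these 9 genes. Gpr85 was the 1 bright gene not called. Uncalled genes alone, with 1 of 1 lower at an unadjusted p under 0.05, were too few to decide. Loss of 1 copy of the segment in the Tg mice remains a candidate explanation. The nearest flanking genes Nxph1 (-0.31) and Mdfic (-0.14) were lower too, and medians near 0 begin beyond them; reduced transcription of an intact segment was not tested, and copy number and insertion site were not analysed here. Of 100 splits of the 10 arrays, 1, the real one, gave as many as its 10 probe sets, and the highest other split gave 3. Those 10 were 2 of Glo1, the transgene itself, and 8 of this 1 stretch, so they are not independent. The splits therefore cannot exclude that the stretch differed between the groups by chance.

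For gene lists chance cannot be excluded: 40 of the 100 splits gave at least the 6 lists of the real split at the preset correlation, and another split gave 11.

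Other lists also set WT replicate 2 apart from the 4 other WT arrays. It was high for striatal markers (10.59 against 10.35 to 10.38), cortical and hippocampal markers (9.45 against 9.33 to 9.35) and thalamic and hypothalamic markers (8.94 against 8.65 to 8.69). It was also high for neuronal markers (12.17 against 12.14 to 12.15), meningeal markers (9.01 against 8.94 to 8.96), blood markers (7.36 against 6.79 to 6.86) and anxiety and stress genes (9.34 against 9.21 to 9.24). It was low for GABA-A receptor genes (9.76 against 10.03 to 10.08) and choroid plexus markers (8.47 against 8.59 to 8.61). Among single genes, 2610001J05Rik read 8.85 there against 9.08 to 9.12, Rgs9 10.41 against 10.09 to 10.15, and Dnah8 6.46 against 6.20 to 6.26.

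Other arrays stood apart for other genes and lists. In WT replicate 4, Ldhb read 11.55 against 11.65 to 11.69, and Per3 9.40 against 9.43 to 9.44. The glutathione list read 9.13 in WT replicate 3 against 9.07 to 9.08, and the heat shock list 10.42 in WT replicate 5 against 10.15 to 10.17. In Tg replicate 5, Btbd9 read 10.92 against 10.67 to 10.70, and Gstm4 8.93 against 9.13 to 9.21. In Tg replicate 3, Fos read 7.18 against 7.40 to 7.50, and Ifit1 8.21 against 7.68 to 7.81.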

How the results depend on the processing

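The settings without both replicate 2 arrays, with the first principal component as a covariate and without the chromosome 6 stretch were chosen after seeing the data; all others were planned. The Glo1 difference stayed past the threshold in all 21 alternatives, between 1.43 and 1.56 log2 units on its brighter probe set 10471675, and the 2 higher probe sets remained 2. The count of lower probe sets was 8 and became 5 among the upper 30% of probe sets, where fewer were tested, 5 under a 1.2-fold minimum and 0 without the chromosome 6 stretch; leaving out single arrays gave 7 to 9. Glo1 neighbours past the list alone numbered 1, but 2 under median centring, array weights and without both replicate 2 arrays, and 0 to 4 with single arrays left out. Gene lists numbered 6, and 0 with an estimated correlation and 0 by fry. At the preset correlation vascular markers were gained in the upper 60% and upper 30% of probe sets, glycolysis and astrocyte lists in the upper 30%, and glutamate receptor and pituitary lists without both replicate 2 arrays; with an estimated correlation none of them passed there. Chromosomes with an excess over the rest numbered 1, and 2 at an unadjusted p under 0.01. These 2 were chromosome 6 with 11 genes (Fisher's exact test adjusted p = 0.00159) and X with 7 (adjusted p = 0.0262), again with genes counted as independent. The causes of these shifts were not tested, except where a smaller set of probe sets is named. Several small values turned direction. Zfand3 went to -0.00012 under median centring, -0.033 under array weights and -0.041 without both replicate 2 arrays, and lay between -0.027 and 0.028 with single arrays left out. The cerebellar list went to -0.054 under array weights (camera adjusted p = 0.349), -0.11 without both replicate 2 arrays and between -0.11 and 0.34 with single arrays left out. Camera's direction turned for the methylglyoxal list in the upper 60% (mean -0.0074) and upper 30% (-0.0015) of probe sets and with single arrays left out (-0.024 to 0.0026), and for the GABA-A list in the upper 30% (0.055). Gh went to -0.027 with the serial number as covariate, and Prl and Gh to -0.38 and -0.37 with the first principal component. With single arrays left out Prl ranged from -1.02 to 1.44, Gh from -0.998 to 1.28, Gabra4 from -0.051 to 0.00036, Gabra3 from -0.015 to 0.044 and Glp1r from -0.0049 to 0.097. The cause was not tested. The labels do not say whether replicate numbers pair the mice. With group means removed, same-numbered arrays correlated between -0.472 and 0.453, and 2 of 5 correlated best with their own number. In the labels, the serial numbers of same-numbered arrays are neighbours in order, but what these numbers mean is not stated. The correlations leave pairing undecided. With the replicate block the Glo1 difference was 1.51, 2 probe sets were higher and 9 lower (Gpr85 gained), 10 genes, 1 neighbour, 5 lists (hindbrain and midbrain lost) and 1 chromosome passed. Arrays give no read depth, and dim probe sets limit what can be seen.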

Other observations

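With WT replicate 2 left out, cerebellar genes were lower in Tg brain. Of 18 cerebellar markers, 16 had lower Tg means, and 10 passed adjusted over the list alone: Gabra6 (-0.29), Cbln3 (-0.28), Cbln1 (-0.25), Neurod1 (-0.24), En2 (-0.21), Zic1 (-0.20), Il16 (-0.20), Pcp2 (-0.18), Car8 (-0.14) and Calb1 (-0.11). None passed over all probe sets; Gabra6 had an adjusted p of 0.274. The list mean was 10.24 ± 0.037 in 5 Tg arrays and 10.35 ± 0.031 in the 4 WT arrays, with no overlap (exact permutation p = 0.007937, the smallest 5 against 4 arrays can give). This test was chosen after seeing the data, and 30 lists had been examined. Over the 30 lists the estimated correlation gave an adjusted p of 0.193 for this list and fry 0.0222. Striatal markers stayed lower in all 14 members (fry adjusted p = 0.0222, estimated correlation adjusted p = 0.193). Other tissue lists shifted as well: hindbrain and midbrain markers were higher in 17 of 19 members (mean 0.089, camera adjusted p = 0.00348, estimated correlation adjusted p = 0.879). Olfactory bulb markers were higher in 12 of 14 (mean 0.16, camera adjusted p = 0.102). Pituitary markers were higher in 9 of 9 (mean 0.53, camera adjusted p = 0.0109, estimated correlation adjusted p = 0.882). That size rested on Tg replicate 2, with a list mean of 8.91 against 6.85 to 6.99 on the other Tg arrays. With Tg replicate 2 left out instead, the mean difference was -0.35. At an unadjusted p under 0.05 the count of probe sets was 3189 without that array, against 640 with it, while calls went from 10 to 11.

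Without WT replicate 2, Cldn5, a tight junction gene of brain endothelium, and Col3a1, a fibrillar collagen, were each the 1 higher member past the threshold over their vascular and meningeal lists. At an unadjusted p under 0.01, 7 genes of the X chromosome appeared, Fgf16 (0.18) and Rbm3os (0.20) higher and Xkrx (-0.24), Mospd1 (-0.21), Il1rapl2 (-0.18), Jade3 (-0.17) and Atg4a (-0.15) lower in Tg. No gene of X passed the adjusted threshold.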
